A study of Homo sapiens with 6 samples.

How the data were processed

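RNA was measured in 6 libraries of the human glioblastoma line 8MGBA, 3 of the parental line and 3 of a line stably transfected with a vector encoding S-SETMAR. Per the labels, libraries were made with a stranded mRNA kit and sequenced as single-end reads. The deposited count table holds raw read counts per gene, not normalized. Per the submitters' processing notes, Trimmomatic 0.38.0, HISAT2 2.4.2, HTSeq 0.9.1 and the GRCh38.p11 build were used, with no role or order given. The strand setting of the counting is not given in the sources used here. The authors' deposited table holds a log fold change, p-value and adjusted p per gene. DESeq2 and DESeq are named in the submitters' processing notes, and their settings are not given in the sources used here.

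The count table had 33107 rows. Of their names, 23573 equal a current symbol, 1697 were matched through an older symbol in the reference and 7837 had no symbol in the reference. In 1 row the column of control replicate 1 carries another name. Among the rows, 3103 are numbered copies of 1224 genes. Of 742 protein-coding genes with such a copy, 55.4% had no read in 5 libraries, against 9.61% of 18239 without one, so genes with copies, HLA genes among them, are uncertain. Of the genes named, 18 share exonic bases with a gene on the opposite strand, and their counts are uncertain to that extent: AQP6, CA9, ATM, ATP5F1A, KCP, CCDC152, CCNE2, CNP, DKK1, NDUFB3, FBN2, HSPE1, IL6, KRT8, TAGLN, SREBF1, RASL12 and UCHL1. Mitochondrially encoded genes had 0 rows and were not analysed here. Count columns of no sample numbered 0.

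The design fixed before the data were examined compared all 6 libraries. Before any test was run, the column of control replicate 1 was found not to hold the same quantity as the other columns (634331 counts and 10.2% of them on antisense-named genes), and it was left out. Control replicates 2 and 3 were compared with S-SETMAR replicates 1 to 3, and the fit of all 6 libraries is reported beside it. Thus the control group rests on 2 libraries.

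Counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test with robust dispersion, TMM normalization, low counts removed by filterByExpr with a minimum count of 10 and a minimum total of 15), and p-values were adjusted by Benjamini and Hochberg's method over 15892 genes. The common dispersion was 0.0166, a biological coefficient of variation of 12.9%. Values per library are CPM scaled by TMM factors. Gene lists were tested with camera in limma 3.58.1 (preset correlation 0.01, two-sided), with an estimated correlation and with fry beside it. Fixed lists numbered 45, of which 44 had at least 5 tested members. DESeq2 1.42.0 was an alternative. Python 3.11.15, pandas 2.3.3, SciPy 1.17.1 and NumPy 2.4.6 were used for tables. Coordinates are from GENCODE 29 on GRCh38.

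Genes named were chosen by a rule fixed before the data were examined. It takes SETMAR, the 10 largest rises and 10 largest falls among genes with a symbol, an adjusted p under 0.05, a mean of at least 1 CPM and non-overlapping groups, up to 4 members with the smallest p and 2 abundant members that did not pass from each list, and the 2 most abundant members of marker lists. XIST and Y-linked genes are not named. The rule was applied to the 5 libraries, and some genes it allows are not reported here. ACTB is named in addition, as a check of depth. For a gene with no counts in a group the fold is a lower bound against 3 counts over the group, and for 1 to 3 counts the ratio has a 95% exact binomial interval.

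The procedure was tested on simulated data with the dispersions of these libraries, 200 changed genes in each of 10 draws over 15892 genes. It recovered 38.5% of 1.5-fold changes (26.9 to 47.8% by draw), 74.5% of 2-fold changes (70.1 to 80.6%) and 94.1% of 4-fold changes (90.9 to 97.0%). Of its calls, 9.44% were unchanged genes, above the 5% aimed at. The simulation changed far fewer genes than the 7737 called in the data, so these shares need not hold for this comparison. Of 1000 unshifted lists 15 had a camera p under 0.05, and the shifted list was found in 10 of 10 draws. Genes were drawn independently of each other, so this does not test the list calls where members vary together.

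Alternatives fixed in advance were other normalizations, filters, tests, a replicate block and leaving out each library. A correction for GC content and exon length, run on the 14517 tested genes (91.3%) that had both, and thinning of counts to the shallowest of the 5 libraries, were added after the data were seen.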

Results

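Gene expression was measured by RNA sequencing in 8MGBA, an established human glioblastoma cell line, and in a derived line stably transfected with a vector that encodes S-SETMAR. SETMAR is a gene that joins a histone methyltransferase (SET) domain to a domain derived from a mobile element, and S-SETMAR is the product named in the labels. The deposited table held 6 libraries, 3 labelled as parental control and 3 as S-SETMAR. The titles of the S-SETMAR samples also contain the word control, and they were grouped by the S-SETMAR part. Control replicates 2 and 3 held 43167230 and 50334648 counts, and S-SETMAR replicates 1 to 3 held 33988630, 36082741 and 34839902. The column of control replicate 1 held 634331 counts. In it the genes named as antisense took 10.2% of the reads (95% Wilson interval 10.2 to 10.3%), against 0.156% and 0.154% in control replicates 2 and 3 and 0.187 to 0.225% in the S-SETMAR libraries. ACTB, the cytoplasmic actin gene, had 84 counts there and 254164 and 364823 in the other controls. This column was not comparable with the others, so the values below compare 2 control with 3 S-SETMAR libraries. This departs from the design fixed in advance, and the fit of all 6 libraries is given beside the main counts.

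SETMAR transcripts were higher in the S-SETMAR line, as a check of the labels. Control replicates held a mean of 17.6 ± 0.0909 CPM (counts scaled by library size; SD, n = 2) and the S-SETMAR libraries 144 ± 15.7 (SD, n = 3). All 3 S-SETMAR libraries lay above both controls. The log2 fold change was 3.03 (SE 0.13, edgeR adjusted p = 4.08e-07), and it was 2.76 (edgeR adjusted p = 0.0444) with all 6 libraries. SETMAR lies at chromosome 3, 4303304 to 4317567, on the plus strand of GRCh38 in GENCODE 29. Gene-level counts do not separate transcripts of the vector from those of the endogenous gene.

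**Figure D1:**
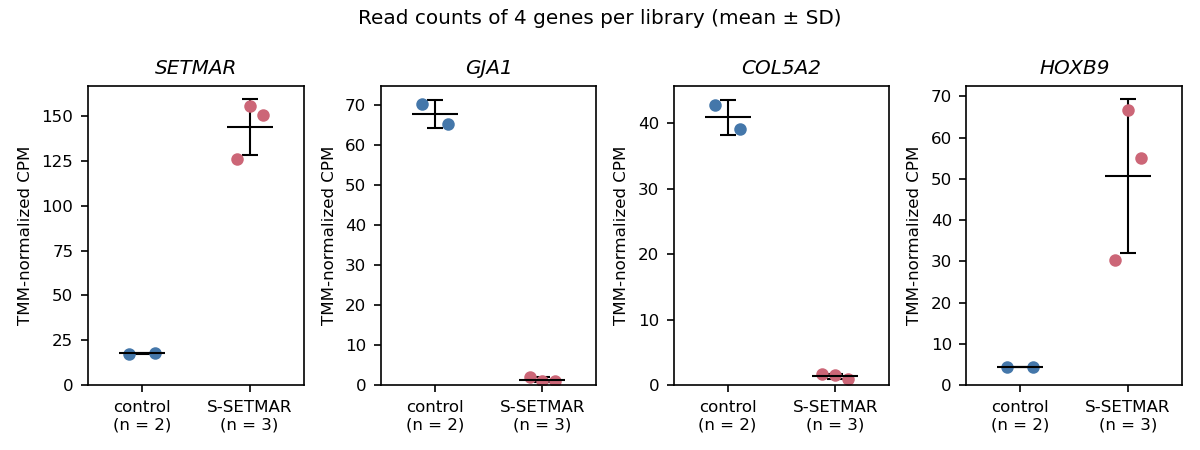
TMM-normalized CPM of SETMAR, GJA1, COL5A2 and HOXB9 in each library (points), with the group mean and SD (bars), for 2 control and 3 S-SETMAR libraries. Mean SETMAR was 17.6 in control and 144 in S-SETMAR libraries, and mean GJA1 was 67.7 and 1.33.

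The question set by the series design was which genes differ between the S-SETMAR line and its parental line. GJA1, which encodes the gap junction protein connexin 43, went from 67.7 ± 3.55 to 1.33 ± 0.618 CPM (log2 fold change -5.68, SE 0.24). COL5A2, a fibrillar collagen gene, went from 40.9 ± 2.64 to 1.37 ± 0.382 CPM (-4.90, SE 0.20), and LUM, the proteoglycan lumican, from 23.2 ± 0.886 to 0.191 ± 0.103 CPM (-6.89, SE 0.27). HOXB9, a homeobox transcription factor gene, rose from 4.35 ± 0.105 to 50.6 ± 18.6 CPM (3.54, SE 0.35). Of 15892 genes tested, 7737 passed an edgeR adjusted p of 0.05, 3948 higher and 3789 lower in the S-SETMAR line. Of these, 2691 changed at least 2-fold, 1655 higher and 1036 lower. With all 6 libraries, as designed, 254 genes passed (129 higher, 125 lower), and without control replicate 2, which leaves 1 control, 4386 passed, 867 of them at least 2-fold higher and 835 at least 2-fold lower. In that fit of 6 libraries, GJA1 (-5.22, edgeR adjusted p = 0.0889) and COL5A2 (-4.52, edgeR adjusted p = 0.078) no longer passed. Of the genes named here other than SETMAR that it tested, 48 kept their direction but were no longer called, 6 turned in sign and 22 kept both direction and side of the threshold. Scaling by library totals alone gave 5049 higher and 2818 lower (2096 and 839 at least 2-fold), and moved the median log2 fold change of all tested genes from 0.032 to 0.17.

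Several genes with steep falls were detected in both controls and had no counts, or 1, over the 3 S-SETMAR libraries. MMP16, a membrane-type matrix metalloproteinase gene, had 691 pooled control counts and none in the S-SETMAR libraries, at least 284-fold lower against a floor of 3 counts over the group. By the same floor ZNF518B was at least 277-fold lower, OCIAD2 272-fold, CCDC152 189-fold and RASL12 151-fold. The axon guidance gene SEMA3E was at least 99.6-fold lower and SLITRK5, a neuronal membrane protein gene, 94.3-fold. A single count remained for ADGRL2 (named LPHN2 in the file), an adhesion receptor gene, a ratio of 1643 (95% exact counting interval 294 to 64959). A single count also remained for NALF1 (FAM155A in the file; ratio 973, interval 174 to 38478) and for PLXDC2 (ratio 604, interval 108 to 23896). These intervals and floors cover counting error only.

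Among the steepest rises, TMEM52 and CFAP74 (KIAA1751 in the file) are neighbours on chromosome 1. TMEM52 lies at 1917590 to 1919273 and CFAP74, a cilium-associated gene, at 1921951 to 2003837. CFAP74 went from 0.0648 ± 0.0568 to 8.79 ± 2.06 CPM (log2 fold change 6.96, SE 0.44). TMEM52 had 1 pooled control count and 250 in the S-SETMAR libraries, a ratio of 202 (95% exact interval 36.0 to 8029). The water channel genes AQP5 (3.48, SE 0.60) and AQP6 (3.71, SE 0.74) and the neighbouring FAIM2 (3.49, SE 0.72) rose together on chromosome 12. AQP5 had 13.6 ± 8.64, FAIM2 3.04 ± 2.38 and AQP6 1.80 ± 1.26 CPM over the S-SETMAR libraries (SD, n = 3). AQP6 (3.40) and FAIM2 (3.17) were no longer called without control replicate 2, nor AQP5 (3.47) and FAIM2 (3.47) without the low-count filter, at folds close to those above. With all 6 libraries AQP5 (3.50) and FAIM2 (3.46) were not called and AQP6 turned lower (-4.31). AQP6 also shares 137 exonic bases with a gene on the opposite strand. FNDC1 (4.14, SE 0.23), KCP (3.41, SE 0.37) and PMAIP1, which encodes the proapoptotic protein NOXA (3.52, SE 0.31), also rose.

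Of 44 gene lists with at least 5 tested members, 11 passed the camera list test with its preset correlation of 0.01, 10 lower and 1 higher. None of the 11 held with an estimated correlation, where the camera adjusted p = 0.814 for each and 1 of the 44 lists had an unadjusted p under 0.05. With all 6 libraries 4 passed, the immediate early, epithelial to mesenchymal transition, HOX and NF-kB lists. By fry's directional test 8 of the 11 passed, as did 10 other lists: the non-homologous end joining, p53 target, histone methyltransferase and demethylase, cadherin, integrin, matrix protease, angiogenic factor, neural stem cell, Notch and receptor tyrosine kinase lists. Counts of members over all genes and counts adjusted over the list alone differed by at most 2 members in each direction for every list.

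**Figure D2:**
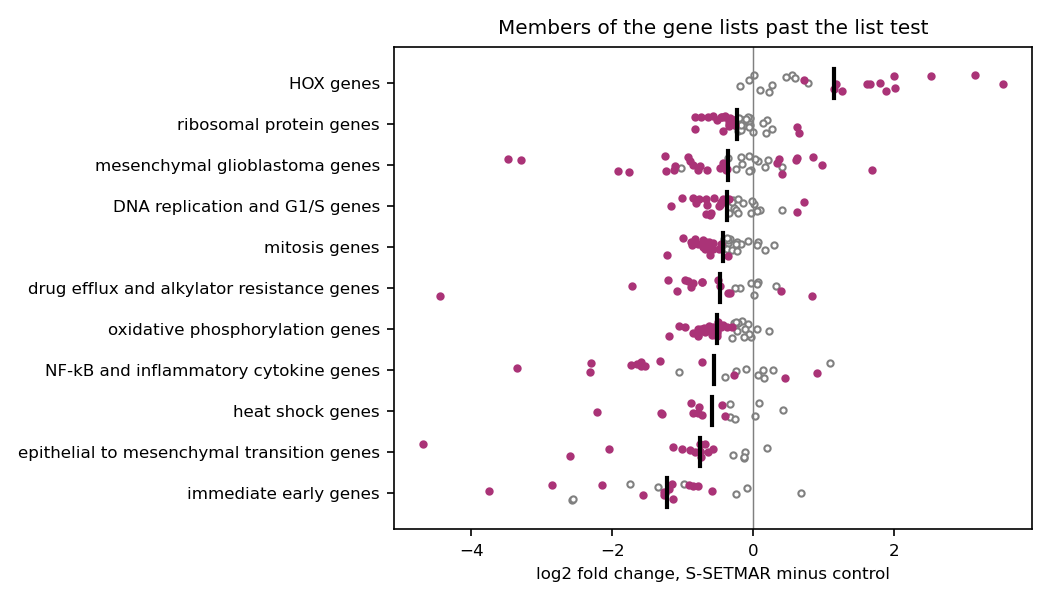
Log2 fold change (S-SETMAR minus control) of each tested member of the 11 lists past the list test. Filled points passed an adjusted p of 0.05, open points did not, and bars mark the list median, which was 1.14 for HOX genes and -1.23 for immediate early genes.

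HOX genes, which set positional identity, were the list that rose: 13 of 23 tested members were higher and 0 lower, and 13 when adjusted over the list alone (camera adjusted p = 0.00105). HOXB8 (log2 fold change 3.14, SE 0.41) and HOXA5 (2.00, SE 0.31) rose with HOXB9. Immediate early genes fell in 14 of 22 members, with 0 higher, and in 15 when adjusted over the list alone (camera adjusted p = 9.67e-07). Among them were ATF3, a stress-induced transcription factor gene (log2 fold change -2.85, SE 0.12), NR4A2, a nuclear receptor gene (-3.75, SE 0.39), and ZFP36, an RNA-destabilizing protein gene (-2.15, SE 0.19). FOS stood at -1.35 (SE 0.99, edgeR adjusted p = 0.338), with 124 ± 125 CPM over the S-SETMAR libraries. Without S-SETMAR replicate 1 it passed at -2.62 (edgeR adjusted p = 4.69e-09), and by limma-voom at -1.83 (adjusted p = 0.0249).

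Epithelial to mesenchymal transition genes fell in 15 of 20 members and rose in 0, the same 15 and 0 by number when adjusted over the list alone (camera adjusted p = 1.63e-05). Examples were the smooth muscle contractile genes CNN1 (-4.68, SE 0.20) and TAGLN (-2.60, SE 0.16) and the N-cadherin gene CDH2 (-0.83, SE 0.11). Mesenchymal glioblastoma genes were lower in 18 and higher in 8 of 39 members, or 19 and 9 when adjusted over the list alone (camera adjusted p = 0.0292). The annexin genes ANXA1 (-3.48, SE 0.18) and ANXA2 (-1.13, SE 0.13) fell. This list no longer passed without control replicate 3 (camera adjusted p = 0.12) or with all 6 libraries (camera adjusted p = 0.478), and its adjusted p over all alternatives ran from 0.00141 to 0.814. NF-kB and inflammatory cytokine genes were lower in 11 and higher in 2 of 22, with the same numbers adjusted over the list alone (camera adjusted p = 0.0156). The cytokine gene IL6 (-2.32, SE 0.21) and the feedback inhibitor genes NFKBIA (-1.74, SE 0.12) and TNFAIP3 (-1.54, SE 0.13) fell, and ICAM1 rose (0.90, SE 0.13). IL6 lies in a chromosome segment where most called genes fell, described below.

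Oxidative phosphorylation genes fell in 28 of 42 members and rose in 0, or 29 and 0 when adjusted over the list alone (camera adjusted p = 2.2e-08). NDUFA4 (-1.19, SE 0.10), NDUFB3 (-1.05, SE 0.12) and ATP5F1A (ATP5A1 in the file; -0.79, SE 0.10) were examples. Ribosomal protein genes were lower in 19 and higher in 2 of 44, as when adjusted over the list alone (camera adjusted p = 0.0014), with RPL7 at -0.83 (SE 0.10) and RPL24 at -0.83 (SE 0.10). With all 6 libraries the ribosomal list turned higher and did not pass (camera adjusted p = 0.0542; 7.54e-05 to 0.814 over all alternatives). Heat shock genes fell in 10 of 16, or 11 when adjusted over the list alone (camera adjusted p = 0.0014), including the chaperone genes HSPH1 (-1.29, SE 0.15), HSPE1 (-1.32, SE 0.16) and HSP90AB1 (-0.78, SE 0.12). NDUFA4, RPL7 and HSPH1 lie in chromosome segments where most called genes fell, described below.

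Mitosis genes fell in 18 of 34 members and rose in 0, or 19 and 0 when adjusted over the list alone (camera adjusted p = 6.69e-05). The mitotic cyclin gene CCNB1 (-0.88, SE 0.14) and the securin gene PTTG1 (-1.22, SE 0.13) were lower. MKI67, the Ki-67 proliferation marker gene, stood at 0.070 (SE 0.13, edgeR adjusted p = 0.673). DNA replication and G1/S genes were lower in 18 and higher in 2 of 34, or 20 and 2 when adjusted over the list alone (camera adjusted p = 0.00105), with the replication clamp gene PCNA at -0.82 (SE 0.11), the clamp loader gene RFC3 at -1.17 (SE 0.15) and the cyclin gene CCNE2 at -1.01 (SE 0.13). RFC3 and CCNE2 lie in chromosome segments where most called genes fell, described below. By fry's directional test the mitosis, DNA replication and heat shock lists had fry adjusted p = 0.16, 0.121 and 0.0525.

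Drug efflux and alkylator resistance genes were lower in 14 and higher in 2 of 23, as when adjusted over the list alone (camera adjusted p = 0.00412). The efflux pump gene ABCG2 (-1.72, SE 0.20) and the quinone reductase gene NQO1 (-1.22, SE 0.13) fell. MGMT, whose product removes alkyl groups from guanine in DNA, had few counts in both lines, with 41 pooled counts in the controls and 2 in the S-SETMAR libraries, a ratio of 25.3 (95% exact interval 6.57 to 216).

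DNA repair, p53 target and histone methyltransferase lists did not pass the camera test. By fry, which does not compare a list with other genes, the non-homologous end joining list had an adjusted p = 0.0324, and the p53 target and histone methyltransferase lists had 0.0235 each. Non-homologous end joining genes, the repair route in which SETMAR has been studied, were higher in 3 and lower in 6 of 18 (camera adjusted p = 0.424). The Ku subunit genes XRCC5 (-0.77, SE 0.11) and XRCC6 (-0.81, SE 0.12) fell, and PRKDC, the DNA-dependent protein kinase gene, stood at -0.015 (SE 0.11, edgeR adjusted p = 0.924). Homologous recombination and Fanconi genes were higher in 4 and lower in 8 of 32 (camera adjusted p = 0.339), with the exonuclease gene EXO1 at -1.22 (SE 0.14). DNA damage checkpoint genes were higher in 2 and lower in 7 of 18 (camera adjusted p = 0.164), with the kinase gene ATM at 0.81 (SE 0.13). Among p53 target genes 4 were higher and 8 lower of 26 (camera adjusted p = 0.548). EDA2R had 157 pooled control counts and none in the S-SETMAR libraries, at least 64.6-fold lower, and GADD45A fell (log2 fold change -1.15, SE 0.10). PMAIP1, given above among the rises, is also a member of this list and was 1 of the 4 higher. Histone lysine methyltransferase and demethylase genes, a list that includes SETMAR, were higher in 18 and lower in 7 of 44 (camera adjusted p = 0.215), with SETD1B at 1.31 (SE 0.12) and SMYD2 at -1.30 (SE 0.11).

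Matrix and adhesion lists held large changes in both directions and did not pass the list test. Collagen genes were higher in 14 and lower in 7 of 26 (camera adjusted p = 0.339), and their median (0.76) and mean (-0.082) differed in sign. COL8A1 fell (log2 fold change -2.84, SE 0.18) as COL5A2 did, and COL1A1, the main fibrillar collagen gene, rose (log2 fold change 0.98, SE 0.15). Other extracellular matrix genes were higher in 15 and lower in 10 of 36 (camera adjusted p = 0.668), with the laminin gene LAMA1 at 1.49 (SE 0.11) and the fibrillin gene FBN2 at -2.08 (SE 0.18). Axon guidance genes were higher in 18 and lower in 11 of 42 (camera adjusted p = 0.339), and passed with the filter of at least 10 reads in every library. That filter drops members that fell to near 0 in the S-SETMAR libraries, SEMA3A, SEMA3D and SEMA3E among them. The members it keeps are thus chosen in part by the outcome, and this pass is no added support. The netrin gene NTN1 rose (2.80, SE 0.24). SEMA3D was at least 65.9-fold lower, and SEMA3A had 385 pooled control counts and 3 in the S-SETMAR libraries, a ratio of 158 (95% exact interval 53.8 to 772). Cadherin and protocadherin genes were higher in 8 and lower in 8 of 25 (camera adjusted p = 0.879), with FAT4 at -6.97 (SE 0.37) and PCDH7 at least 77.4-fold lower. Median and mean also differed in sign for the other extracellular matrix (-0.073 and 0.056), axon guidance (0.37 and -0.48) and cadherin (0.29 and -1.26) lists.

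Markers of astrocytes and of other cell types did not pass the list test (camera adjusted p at least 0.298). Astrocyte markers were higher in 6 and lower in 5 of 19, with GJA1 lower and the glutamine synthetase gene GLUL higher (0.37, SE 0.11). GLUL was no longer called without control replicate 2 (0.40), without control replicate 3 (0.33) or with all 6 libraries (0.80). Neuron markers were higher in 4 and lower in 5 of 16, with ELAVL2, a neuronal RNA-binding protein gene, at -7.39 (SE 0.35) and UCHL1 at -0.44 (SE 0.10). Endothelial markers were higher in 5 and lower in 0 of 15 (camera adjusted p = 0.298), with the receptor gene TIE1 at 2.21 (SE 0.19). Pericyte and fibroblast markers were higher in 4 and lower in 6 of 14, with the proteoglycan gene CSPG4 at 2.10 (SE 0.15). Epithelial markers were higher in 6 and lower in 3 of 17, with the keratin genes KRT8 at 0.73 (SE 0.15) and KRT17 at -2.86 (SE 0.17). Oligodendrocyte markers were higher in 3 and lower in 1 of 8, with CNP at 0.73 (SE 0.11), and microglia and macrophage markers higher in 1 and lower in 2 of 6, with CD68 at 1.07 (SE 0.16). With all 6 libraries KRT8 (-3.80), CNP (-5.15), CD68 (-0.055) and UCHL1 (0.10) turned in sign, and KRT8 was not called without control replicate 2 (0.58). Median and mean differed in sign for the astrocyte (0.37 and -0.057) and microglia (0.075 and -0.043) lists.

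The authors' deposited table of the same comparison called 8750 of the 15882 genes tested in both, at its adjusted p under 0.05. Of these, 7496 were also called by edgeR on 5 libraries, all in the same direction. In the authors' deposited table the log fold change of SETMAR was 2.94, of GJA1 -5.46 and of COL5A2 -4.79. Across genes, not independent replicates, the fold changes of both tables correlated at 0.951 with 5 libraries and at 0.339 with 6. Of 9245 genes with no read in any of the 6 deposited count columns, 216 had a log fold change in the authors' deposited table, so it may not have been made from these columns as they stand.

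Log2 fold changes also differed by chromosome segment. In windows of 50 neighbouring tested genes, the first window of chromosome 1 (14404 to 2405444) had a median of 1.21, with 44 genes higher and 0 lower (0.78 after a GC and length correction). Windows on distal chromosome 1 (229626234 to 241999073, median -0.87, corrected -0.75), chromosome 8 (98024851 to 118952200, median -0.71, corrected -0.49) and chromosome 13 (18195297 to 29595688, median -0.84, corrected -0.66) were low. These windows were chosen after their values were seen.

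**Figure D3:**
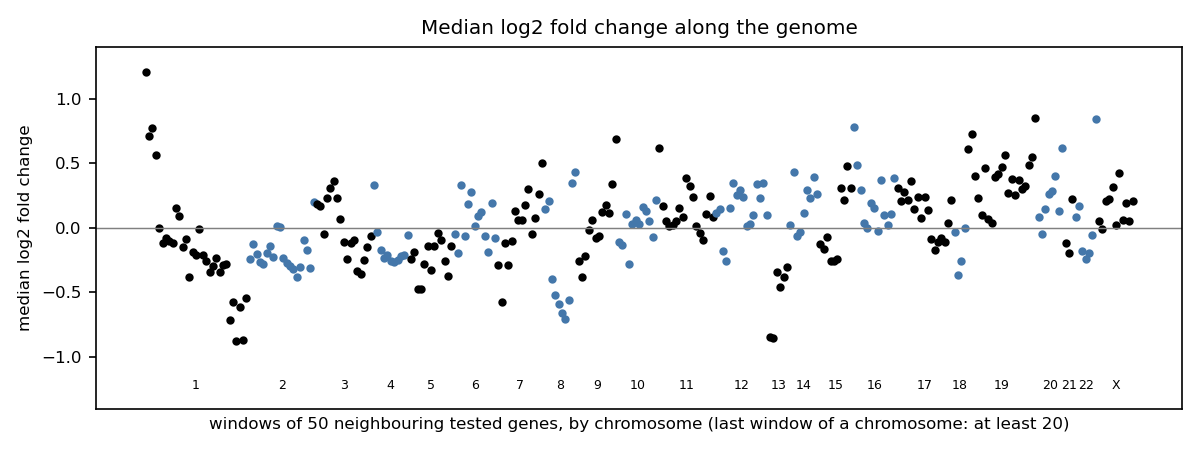
Median log2 fold change (S-SETMAR minus control) of windows of 50 neighbouring tested genes in genome order (the last of a chromosome holds fewer, and those under 20 genes are not drawn), alternating black and blue by chromosome. The first window of chromosome 1 stands at 1.21 and a window of chromosome 13 at -0.84.

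No vector-only line was among the libraries, so transfection, selection and the S-SETMAR product were not separated. The labels call the replicates biological and give no more on how they were raised, so p-values measure only the spread between these libraries.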

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

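The tests of the 100 most abundant control genes in control replicate 1, of GC content as the whole cause, and of the genes near 0 were chosen after the result was seen. Genes named as antisense took 10.2% of the reads of control replicate 1, a column outside the comparison, against 0.154 to 0.225% in the other 5 libraries. A shallow library counted like the others is argued against, because its share of reads in the 100 most abundant control genes was 0.062 of theirs, and a shift of the counts against the names is too, since the highest Spearman rho with control replicate 2 over 400 shifts was 0.365. Across 4522 ordered pairs of genes that overlap on opposite strands, its counts followed the partner gene more closely than the gene itself, with a difference in rho of 0.132 (0.276 against 0.144). In the other 5 libraries rho with the partner was at most -0.060 and rho with the gene itself at least 0.989. Each of these 5 is part of the mean it was compared with, so the 0.989 was partly fixed in advance. Counting on the opposite strand is consistent with these values, and no biological explanation was tested.

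The 5 libraries make 10 splits into 2 and 3, too few for a share under 0.05: the real split, with 7737 genes changed, was the 1 with as many, and the highest of the others called 0 by edgeR and by limma-voom, with 3576 genes at an unadjusted p under 0.05. Every other split mixes both lines in a group, which puts the difference between lines into its spread. Their 0 calls therefore give no measure of chance. Copy number differences as the main cause of the 7737 calls stay open. Windows of up to 50 genes explained 12.4% of the variance of log2 fold changes, above the 2.62% that was highest of 100 permutations. After the GC and length correction they explained 8.68%, above a highest permuted value of 2.58%. The uncorrected share was below the bound set in advance against that cause. A share of variance weighs genes by the size of their change and does not count calls, so it cannot decide this. A trend with GC content and length as the whole cause is argued against, since after its removal 77.7% of the 7292 genes called among the 14517 with GC content and length stayed past the threshold in the same direction. A part played by it stays open: 68.6% of these 7292 genes kept at least 0.67 of their fold change, and of the genes called in each fit with 1 library left out the share was 54.5% (5740 genes, without control replicate 3) to 85.3% (4293 genes, without control replicate 2), so gene set and library change together, and the median log2 fold change went from -0.20 in the genes of lowest GC content to 0.61 in those of highest. The S-SETMAR product, selection and clonal drift stay open too, as the design does not separate them.

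In the S-SETMAR line 12 genes with at least 5 CPM in the controls were at or under 0.1 CPM, among them ADGRL2, FAT4, ELAVL2, MMP16 and OCIAD2, and the reverse held for 1 gene, CFAP74. Of the 12, 0% had an expected pooled S-SETMAR count of 3 or less, the smallest being 571. Choosing genes at 5 CPM or more fixed that outcome in advance, so it was no test of depth. It shows only that the S-SETMAR libraries were deep enough to detect these genes at their control level. Loss of the surrounding DNA stays open, as 2 of 9 nearest expressed neighbours fell at least 2-fold (22.2%, 95% exact interval 2.81 to 60.0%), too few to decide. Of all genes at 1 CPM or more in control, 5.99% fell at least 2-fold, a share inside that interval. Silencing of these genes, by S-SETMAR or in the cells the line grew from, was not tested.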

How the results depend on the processing

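The GC and length correction and the thinning were chosen after the data were seen. SETMAR kept its direction and call under every alternative run (log2 fold change 2.76 to 3.23). Leaving out control replicate 1 is the reported fit. With all 6 libraries 254 genes passed (129 higher, 125 lower), all 254 at least 2-fold, 4 lists passed, and 254 calls were shared with the authors' deposited table. Leaving out 1 of the 5 libraries gave 4386 to 8452 genes (2011 to 4279 higher, 2375 to 4173 lower), 1702 to 3114 of them at least 2-fold, and 10 to 12 lists. The lowest count, without control replicate 2, rests on 1 control, assumed to vary like the S-SETMAR libraries. Lists called numbered 0 with an estimated correlation (1 at an unadjusted p under 0.05) and 18 by fry (8 of the 11 and 10 others). With an adjusted p under 0.01 on both sides, calls shared with the authors' deposited table numbered 4969, as fewer genes pass. The corrected and thinned fits called 7253 (of the 14517 genes with GC and length) and 7563 genes, of which 5657 and 7394 were also called in the reported fit. The filter of at least 10 reads in every library called 7035 genes and 12 lists, the axon guidance list gained. It drops members of that list that fell to near 0 in the S-SETMAR libraries, so this gain is no added support. The replicate block called 8720 genes and 15 lists, the interferon, unfolded protein, TGF-beta and BMP, and neural stem cell lists gained. In the block S-SETMAR replicate 1 has no control of its number, so it adds nothing to the group effect. The block is therefore close to the fit without that library, and little spread is left to measure error. The same-numbered libraries deviated together at a correlation of 0.0142 and 0.00615, so with only 2 shared numbers they were not taken as pairs. Signs turned with all 6 libraries for AQP6 (-4.31), PRKDC (0.45), UCHL1 (0.10), KRT8 (-3.80), CD68 (-0.055), CNP (-5.15) and the ribosomal protein list (camera adjusted p = 0.0542). PRKDC also turned with library totals only (0.12) and with the block (0.048), and ran from -0.099 to 0.065 with 1 library left out. MKI67 turned with the block (-0.021) and the GC and length correction (-0.034), and ran from -0.028 to 0.18 with 1 library left out. FOS, not called in the reported fit, was called by limma-voom (-1.83). It was also called with the block (-2.62) and without S-SETMAR replicate 1 (-2.62), whose group effects rest on the same libraries. AQP6, FAIM2, GLUL and KRT8 were no longer called without control replicate 2, GLUL also without control replicate 3, and FAIM2 and AQP5 without the low-count filter. The cause of these changes was not tested.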

Other observations

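Other fixed lists that did not pass the list test held large single changes. The Wnt antagonist gene DKK1 had 102 pooled control counts and none in the S-SETMAR libraries, at least 42.0-fold lower, in a list with 10 higher and 4 lower of 31. The Notch target gene HES1 fell (log2 fold change -3.74, SE 0.19), in a list with 6 higher and 4 lower of 19. Interferon response genes were higher in 12 and lower in 3 of 35 (camera adjusted p = 0.298), with ISG15 at 1.71 (SE 0.25) and IFI44 at -2.71 (SE 0.32). Cholesterol and fatty acid synthesis genes were higher in 12 and lower in 11 of 33, with the regulator gene SREBF1 at 2.28 (SE 0.14). Hypoxia and glycolysis genes were higher in 9 and lower in 4 of 36, with the carbonic anhydrase gene CA9 at 2.70 (SE 0.33). Unfolded protein and integrated stress response genes were higher in 8 and lower in 4 of 30, with DDIT4 at 1.24 (SE 0.16) and ATF3, given above, among those that fell. In the authors' deposited table PPP1R15A (-1.14) and ATF4 (-0.81) of this list were also lower. Cancer-testis antigen genes were higher in 4 and lower in 5 of 20, with MAGEA1 at -5.19 (SE 0.32). Only 7 of 22 antigen presentation genes were tested, and CD74, the invariant chain gene, was the 1 that fell (-3.55, SE 0.29).

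Among the remaining lists, angiogenic factor genes were higher in 4 and lower in 10 of 26, matrix protease and inhibitor genes in 8 and 11 of 33, integrin genes in 5 and 8 of 17, and receptor tyrosine kinase and RAS feedback genes in 6 and 9 of 27. TGF-beta and BMP response genes were higher in 6 and lower in 8 of 27, neural stem cell genes in 5 and 8 of 20, and proapoptotic and antiapoptotic genes in 7 and 8 of 32. Proneural glioblastoma and glial progenitor genes were higher in 6 and lower in 2 of 13, and replication-dependent histone genes in 3 and 0 of 14. None of these passed the camera test with its preset correlation in the reported fit. The TGF-beta and BMP list passed it without S-SETMAR replicate 1, and the replication-dependent histone list without S-SETMAR replicate 3. With the replicate block the TGF-beta and BMP list and the neural stem cell list passed it. Median and mean differed in sign for the Wnt (0.20 and -0.079), cholesterol (-0.16 and 0.082) and apoptosis (-0.022 and 0.09) lists.

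The windows described here and their correction for GC content and length were chosen after the result was seen. Windows with a median beyond 0.5 numbered 30 of 300, 14 low and 16 high, where the last window of a chromosome holds the genes left over and 1 of the 16 holds 13 genes, and held 13.7% of the called genes placed in windows. After the GC and length correction 8 of the 14 low and 5 of the 16 high windows stayed beyond 0.5. On distal chromosome 1 all 6 windows from 193059422 to 248919946 were low, at -0.54 to -0.87. This segment holds ATF3 (212565334 to 212620777), SMYD2 and EXO1, and the high first window of chromosome 1 holds TMEM52, CFAP74 and ISG15. CCNE2 (94879770 to 94896678) lies in a low window of chromosome 8 (81732434 to 98036716, median -0.66, corrected -0.40, 36 genes lower and 2 higher). The low windows of chromosomes 7 and 8 did not stay beyond 0.5 after the correction, and those of chromosomes 1 and 13 did. HSPH1 and RFC3 lie in a low window of chromosome 13 (29764371 to 43786908, median -0.85, 37 genes lower and 1 higher). RPL7 lies in another of chromosome 8 (65717510 to 81732903, median -0.59, 32 lower and 0 higher). NDUFA4 and IL6 lie in a low window of chromosome 7 (6161776 to 23470467, median -0.58, 32 lower and 1 higher). These are examples, not a full list, and for such genes the direction of change was shared by many neighbours. As a hypothesis, differences in the copy number of these segments may contribute there, although windows explained 12.4% of the variance over all genes (8.68% after the GC and length correction). DNA was not measured.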
